A study of Sus scrofa with 15 samples.

How the data were processed

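Total RNA from Longissimus muscle of 15 pigs at 20 kg body weight was measured on 1-colour Agilent arrays, 1 pig per array. The pigs belonged to the low_RFI line (RFIneg, n = 7) or the high_RFI line (RFIpl, n = 8). Per the labels, 150 ng of RNA from each frozen sample was amplified and labelled with Cy3. Per the file headers, scanner signals are intensity values from Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09), after its own background subtraction and detrending and with no normalization between arrays. The same files hold other columns, per the file headers, which flag spots as well above background, non-uniform or saturated. The deposited table gives log2 values made by the authors, for whom R 2.10.0 is named. On the files these were found to be log2 of the processed signal minus each array's median over the 29364 spots listed, with a largest difference of 4.93e-08. How those spots were chosen is not stated, and the table served only as an alternative.

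The comparison started from the scanner signals. Control spots and spots with a non-uniformity flag were left out, and spots of 1 probe were averaged. Log2 processed signal minus the array's 75th percentile over non-control probes is called the level below. A probe was tested when it was well above background on at least 7 of the 15 arrays and had at least 4 values in each line, which kept 31984 of 43603 probes. Names came from the files' accessions and symbols and from a RefSeq gene table of the pig assembly. Of all probes, 12134 had 1 gene symbol, 838 had 1 gene known only by a LOC name, and 30631 had several genes or none. Each gene was represented by its tested probe of highest mean level, which gave 4653 genes. The 371 distinct LOC-named genes among the tested probes are not named in the text, and 684 symbols had no tested probe. Through synonyms in the gene table, the list members MKI67, CTSL and HSPA1A were measured as NIFK, CTSV and HSP70.2; MTERF3 and its older symbol MTERFD1 stayed apart in the counts.

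Lines were compared as low_RFI minus high_RFI, two-sided, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0 and version 1.17.8 of the data.table package. Benjamini-Hochberg adjustment ran over probes, over genes or over lists, and calls were made at an adjusted p under 0.05. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Of 31 lists, 30 had at least 5 tested members. The sex-linked list had 1 tested gene of 2 on the array and was not tested, and the sex of the pigs is not in the labels. For each pig the mean level over a list was also compared between lines by an exact permutation test over all 6435 splits, two-sided, whose smallest possible p is 0.000155. With slide as a random block and with a trended, robust fit, the lists were tested by the preranked form of camera.

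The tests, lists, thresholds, filters and most alternatives were chosen before the data were examined. Blocks for runs of pig numbers, every comparison between those runs, splits balanced by them and the cell cycle list without NIFK were chosen after seeing the data. The text names genes by a rule: up to 12 genes per line of largest difference among those that passed; where fewer than 5 passed, the genes of smallest p up to 10 per line; and up to 4 members of smallest p from each called list and from 11 core lists. Genes named outside this rule are said to have been chosen after their values were seen. Alternatives covered background correction (normexp with offset 50), quantile and median normalization, the deposited values, dim and outlier spots, slide, replicate number, the limma model, array weights, the probe per gene, thresholds, and leaving out each array.

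Between 26908 and 34644 probes per array were well above background, and no spot was saturated. The number of pigs limits the precision: the median standard error of a gene's log2 difference was 0.13. Tested on simulated data from the 4653 genes, the fit recovered 16.8% of genes changed by 25%, 68.0% of genes changed 1.5-fold, 82.0% of those changed 2-fold and 96.8% of those changed 3-fold, with 4.63% of 691 calls false. Those genes were simulated as independent, which real genes of a list are not. Each simulation changed 200 genes, which makes the adjusted threshold easier to reach than where few genes differ. The recovered shares therefore overstate what can be found where few genes differ.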

Results

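Gene expression was measured in Longissimus muscle of pigs at 20 kg body weight from lines selected in opposite directions on residual feed intake (RFI). RFI is the feed an animal eats beyond what its maintenance and growth are predicted to need, so low_RFI pigs are the more efficient ones. The low_RFI line had 7 pigs and the high_RFI line 8, all fed ad libitum, each on its own array. From 61.7% to 79.5% of the 43603 non-control probes were well above background on an array, and the 75th percentile of the processed signal ran from 319 to 440. Levels correlated between arrays across probes at 0.974 to 0.991, with a median of 0.983 both within and between lines; probes are not independent replicates. The first principal component held 17.9% of the variance and separated pigs numbered 1 to 8 in the array names (n = 8) from pigs numbered 55 to 62 (n = 7), and each set held both lines. The arrays lay on 4 slides, each with both lines.

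**Figure D1:**
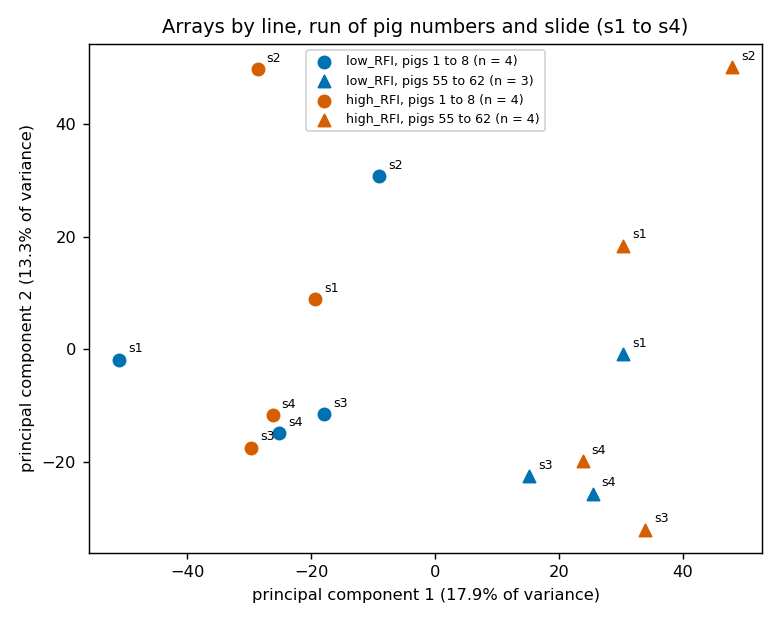
The arrays on their first (17.9% of variance) and second (13.3%) principal components of log2 level; each point is 1 pig, with colour for line and shape for the run of pig numbers. The first axis parts pigs 1 to 8 from pigs 55 to 62, and both lines lie on both sides.

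The question was which genes differ in muscle between the RFI lines at this weight. MTERF3, a mitochondrial protein of the transcription termination factor family, was 1.49-fold higher in high_RFI, with a level of 1.75 ± 0.17 (SD, n = 7) in low_RFI and 2.32 ± 0.13 (SD, n = 8) in high_RFI. Every high_RFI pig lay above every low_RFI pig, as 0 of 56 pairs had the low_RFI pig higher (log2 difference -0.57 ± 0.087 SE, limma adjusted p = 0.035). MTERF3 lies on chromosome 4 of the Sscrofa11.1 assembly, from 40376146 to 40399614. Other probes carry its older symbol MTERFD1 and gave -0.50 ± 0.089 (SE), also with 0 of 56 pairs the other way, but did not pass (adjusted p = 0.0959). Within the 4 slides MTERF3 differed by -0.44, -0.70, -0.53 and -0.72, within the runs of pig numbers by -0.71 and -0.42, and with slide as a fixed block by -0.59, where its call ended (adjusted p = 0.0597, within a range of 0.00981 to 0.344 over 30 alternatives). The call held in 12 of those 30, and leaving out 1 pig ended it for 10 of the 15 pigs, while the log2 difference stayed between -0.60 and -0.48.

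MTERF3 was the 1 gene of 4653 to pass. The genes of next smallest p that were higher in high_RFI did not pass with all pigs; NUDT2 passed without low_RFI replicate 2 (adjusted p = 0.0242) and HSDL2 without high_RFI replicate 5 (0.0322). Among them, NUDT2, which hydrolyses diadenosine tetraphosphate, had a log2 difference of -0.65 ± 0.12 SE (1.57-fold higher in high_RFI, adjusted p = 0.134), with 1 of 56 pairs the other way. CPT1B, the muscle enzyme that passes long-chain fatty acids to carnitine for entry into mitochondria, gave -0.53 ± 0.11 SE (1.44-fold, adjusted p = 0.194), with all 3 of its probes lower in low_RFI. HSDL2, a peroxisomal short-chain dehydrogenase, gave -0.57, the amino acid transporter SLC38A4 -0.72, the DNA polymerase POLL -0.47, the homeobox factor HOXC4 -0.34 and PHTF1 -0.43 (adjusted p from 0.194 to 0.26). OAZ3, an antizyme of polyamine synthesis, gave -0.68, or -1.22 with normexp, and its other probe gave -3.32 (mean of both -2.00).

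Toward low_RFI, 0 genes passed limma; 50 were at an unadjusted p under 0.01, against 32 toward high_RFI and 47 that chance gives in both directions. ANGPT1, a ligand of the endothelial receptor TEK, had the smallest p, with a log2 difference of 0.51 ± 0.11 SE (1.42-fold, adjusted p = 0.194) and all 56 of 56 pairs in that direction. SLC7A11, the cystine and glutamate exchanger, gave 1.18 ± 0.26 SE (2.26-fold, adjusted p = 0.213, 55 of 56 pairs), but was well above background on 8 of 15 arrays and gave 0.028 with normexp background correction. The secreted protein C1QTNF3 gave 0.78, the water channel AQP11 0.34, the DNA primase subunit PRIM2 0.41, the ubiquitin ligase TRIM13 0.52, the O-fucosyltransferase POFUT1 0.26, ZCCHC3 0.36 and the ribosomal protein RPL14 0.41, the last in 6 of 6 probes (adjusted p from 0.213 to 0.344). EDC3, an mRNA decapping factor, gave 0.38, but 1 of its 3 probes gave -0.045 and the mean of its probes 0.12. With normexp, ANGPT1 gave 0.25, PRIM2 0.085 and TRIM13 0.11. In all, 6 symbols had lines that did not overlap (ANGPT1, EDC3, AQP11, POFUT1, and MTERF3 and MTERFD1, which are 1 gene), so 5 genes, against 1.43 symbols that chance gives, or 0.0311%.

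**Figure D2:**
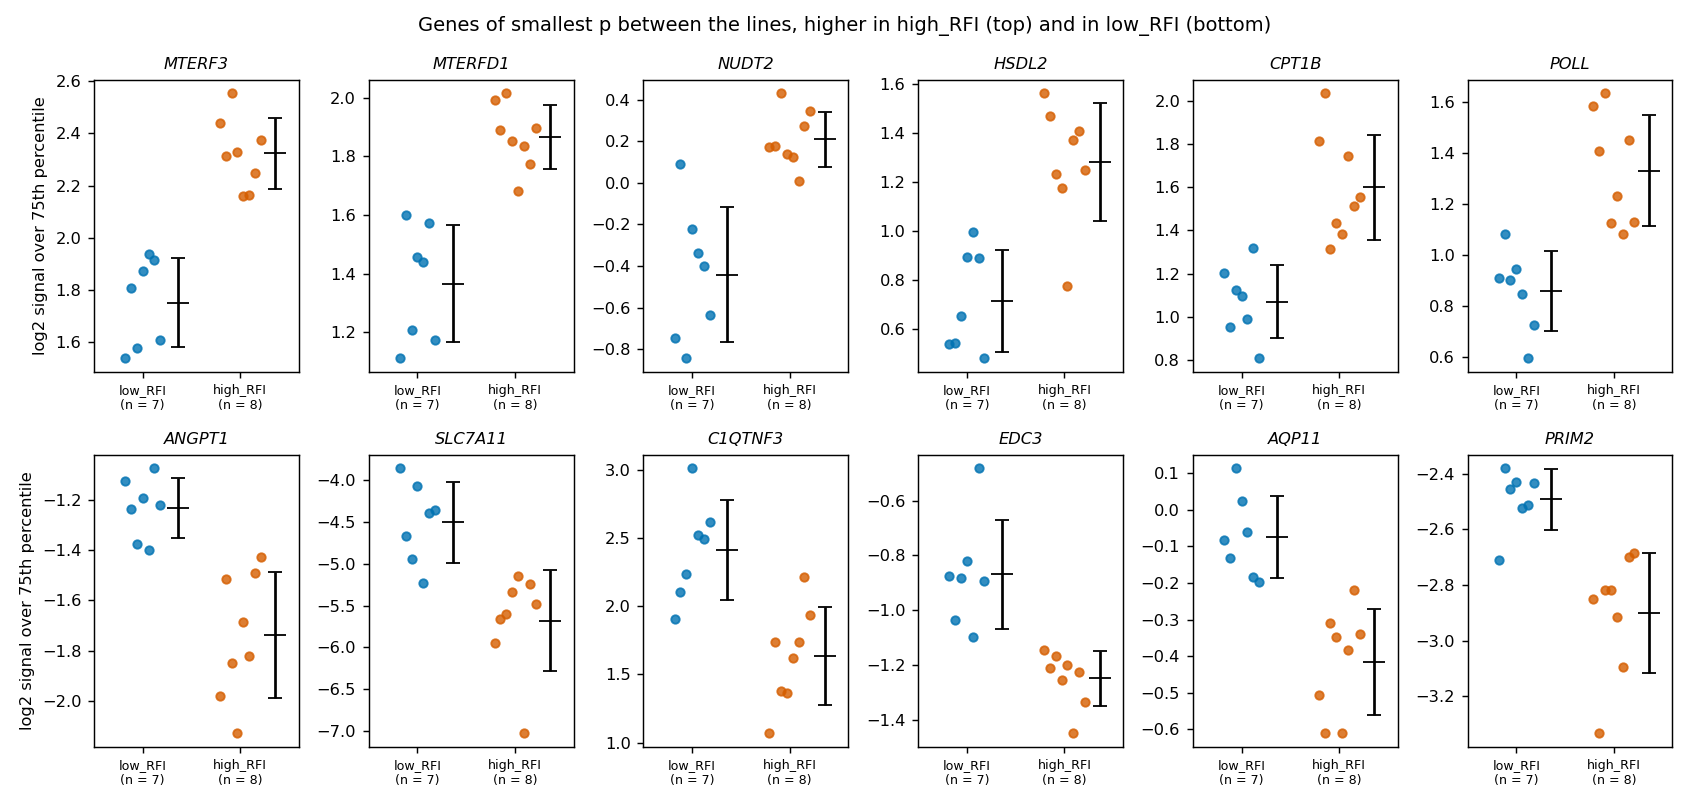
Level (log2 signal relative to the array's 75th percentile) of named genes in each pig, by line, with the mean and SD; n = 7 for low_RFI and 8 for high_RFI. MTERF3 is the gene that passed, with means of 1.75 and 2.32 and no overlap between the lines.

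Over probes, limma called 0 of 31984 (smallest adjusted p 0.103), with 2132 at an unadjusted p under 0.05 where chance gives 1599. Among genes, 336 were at an unadjusted p under 0.05 where chance gives 233.

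Lists of genes of 1 function were compared to ask which muscle processes shifted together. Cytosolic ribosomal proteins, which build the ribosome, were higher in low_RFI in 37 of 39 measured members, by a mean log2 difference of 0.12, with a level of 7.76 ± 0.090 (SD, n = 7) against 7.63 ± 0.074 (SD, n = 8). RPL14 gave 0.41, RPL30 0.27, RPS16 0.26 and RPSA 0.20; 1 of 3 RPS16 probes gave -0.14, and their mean 0.15. Camera called the list (adjusted p = 1.42e-10), with adjusted p = 0.838 with an estimated correlation and 0.19 in the exact permutation test over pigs. The difference was 0.11, 0.19, 0.15 and 0.046 in the 4 slides, 0.17 and 0.056 in pigs 1 to 8 and 55 to 62, and 0.12 with slide as a fixed block (adjusted p = 7.31e-09); it was 0.076 with quantile normalization (4.89e-05) and 0.18 with normexp (6.31e-17). Of its members 13 were at an unadjusted p under 0.05; 0 passed limma over all genes and 0 adjusted over the list alone.

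Cell cycle genes were higher in low_RFI in 19 of 19 members, by a mean of 0.27, with a level of -0.41 ± 0.21 (SD, n = 7) against -0.68 ± 0.17 (SD, n = 8). The replication helicase subunit MCM3 gave 0.58, BIRC5, a chromosomal passenger protein, 0.43, the mitotic kinase CDK1 0.48 and its cyclin CCNB2 0.45, for which 1 of 2 probes gave -0.049. With normexp MCM3 gave 0.075, CCNB2 0.00064 and the list 0.13 (adjusted p = 0.00176). The list was called by camera (adjusted p = 3.8e-06), with adjusted p = 0.633 with an estimated correlation and 0.19 in the exact permutation test. The difference was 0.47, 0.074, 0.0040 and 0.38 in the slides, 0.14 and 0.41 in the runs of pig numbers, and 0.25 with slide as a block (adjusted p = 1.89e-05). Of its members 6 were at an unadjusted p under 0.05, 0 passed limma over all genes and 0 adjusted over the list alone. NIFK, a different gene from the proliferation marker MKI67, was measured in its place through a synonym in the gene table; without it 18 members gave 0.27 (adjusted p = 4.32e-06).

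Heat shock and protein folding genes were higher in low_RFI in 15 of 16 members, by a mean of 0.30, with a level of 3.78 ± 0.44 (SD, n = 7) against 3.48 ± 0.18 (SD, n = 8). The small heat shock protein HSPB1 gave 0.62, the mitochondrial chaperonin HSPE1 0.30 and the endoplasmic reticulum chaperones HSPA5 and HSP90B1 0.25 and 0.27. Camera called the list (adjusted p = 0.00024), with adjusted p = 0.975 with an estimated correlation and 0.787 in the exact permutation test; 4 members were at an unadjusted p under 0.05, 0 passed limma over all genes and 0 adjusted over the list alone. Low_RFI replicates 2 and 7 stood highest, at 4.55 and 4.26. Without replicate 2 the mean was 0.17 (camera adjusted p = 0.0161), and without replicate 7 it was 0.22 (0.015). The other low_RFI pigs lay from 3.46 to 3.69 and the high_RFI pigs from 3.19 to 3.67. The difference in mean level thus rested mainly on replicates 2 and 7. The slides gave 0.64, 0.096, -0.055 and 0.38, the runs of pig numbers 0.33 and 0.26, and slide as a block 0.28 (adjusted p = 0.00265).

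Toward high_RFI, genes of fatty acid uptake and beta-oxidation were higher in 19 of 25 members, by a mean log2 difference of -0.15, with a level of 2.36 ± 0.079 (SD, n = 7) in low_RFI against 2.51 ± 0.11 (SD, n = 8). CPT1B gave -0.53 and DECR1, which handles unsaturated fatty acids in beta-oxidation, -0.64 ± 0.16 SE (1.56-fold higher in high_RFI, 2 of 56 pairs the other way). HADHA and HADHB, the subunits of the mitochondrial trifunctional protein, gave -0.24 and -0.22. Adjusted over the list alone, CPT1B (limma adjusted p = 0.00618) and DECR1 (0.0138) passed, so 2 members, against 0 over all genes. Camera called the list (adjusted p = 0.000194), with adjusted p = 0.633 with an estimated correlation and 0.19 in the exact permutation test. The slides gave -0.14, -0.16, -0.17 and -0.13, the runs of pig numbers -0.21 and -0.069, and slide as a block -0.15 (adjusted p = 0.00021); normexp background correction ended the call at -0.10 (adjusted p = 0.0965).

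Nuclear-encoded oxidative phosphorylation genes, the respiratory chain and ATP synthase, were higher in high_RFI in 27 of 32 members, by a mean of -0.072, with a level of 6.58 ± 0.17 (SD, n = 7) against 6.65 ± 0.18 (SD, n = 8). The complex I subunits NDUFAB1, NDUFB9 and NDUFS6 gave -0.28, -0.24 and -0.18, and COX6C of complex IV gave -0.15 but 0.027 with normexp. Camera called the list (adjusted p = 0.00839), with adjusted p = 0.975 with an estimated correlation and 0.996 in the exact permutation test, and 0 members were at an unadjusted p under 0.05 or passed limma over all genes or adjusted over the list alone. With normexp the mean was -0.0071 and the test turned toward low_RFI (adjusted p = 0.996). The slides gave 0.13, -0.12, -0.20 and -0.18, slide as a block gave -0.089 (adjusted p = 0.0018), and the runs of pig numbers gave -0.18 and 0.065. The call was lost without low_RFI replicate 1 (-0.046, adjusted p = 0.101) or 3 (-0.027, 0.404), or high_RFI replicate 2 (-0.051, 0.0516), 7 (-0.049, 0.135) or 8 (-0.048, 0.11), and the mean was -0.12 without high_RFI replicate 5 and -0.11 with quantile normalization.

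Slow type I fibre proteins were higher in high_RFI in 13 of 14 members, by a mean of -0.30, with a level of 5.36 ± 0.57 (SD, n = 7) in low_RFI against 5.66 ± 0.50 (SD, n = 8). The light chain MYL6B gave -0.98, myosin binding protein MYBPC1 -0.39, the Z-disc protein MYOZ2 -0.58 in 11 of 11 probes lower in low_RFI, and myoglobin (MB) -0.30; without low_RFI replicate 3 MYOZ2 gave -0.35 and MB -0.15. The list passed in camera (adjusted p = 0.00902), with adjusted p = 0.975 with an estimated correlation and 0.968 in the exact permutation test; 0 members were at an unadjusted p under 0.05 or passed limma over all genes or adjusted over the list alone. The slides gave -0.015, -0.15, -1.16 and 0.068 and the runs of pig numbers -0.48 and -0.040, with -0.33 for slide as a block (adjusted p = 0.00408). The call was lost with normexp (-0.24, adjusted p = 0.151) and without low_RFI replicate 3 (-0.16, 0.203), high_RFI replicate 7 (-0.26, 0.113) or high_RFI replicate 8 (-0.25, 0.086), and the mean was -0.48 without low_RFI replicate 6. Fast type II fibre proteins gave 0.030 with 10 of 13 higher in low_RFI (camera adjusted p = 0.861), among them MYH4 at 0.12, MYH1 at -0.076, TNNI2 at 0.069 and TNNC2 at 0.060; single probes of MYH4 and TNNC2 went the other way.

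**Figure D3:**
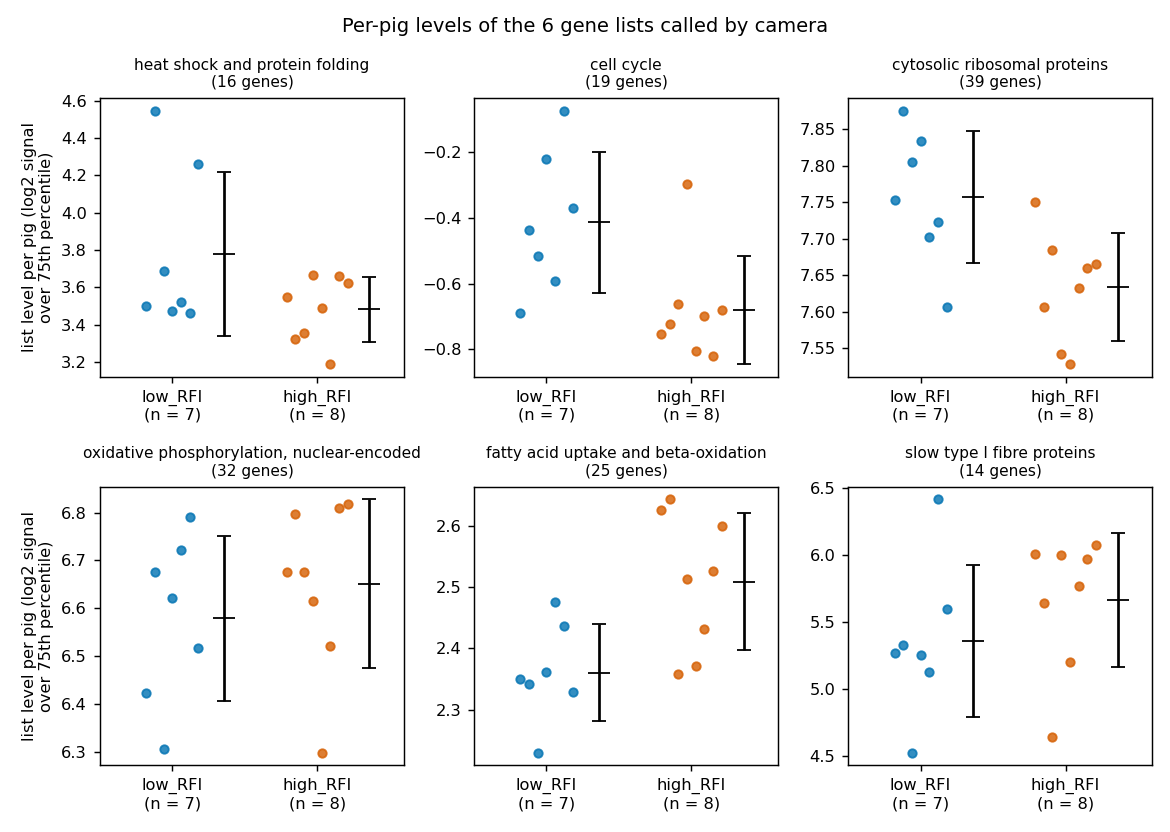
Mean level of each called list in each pig (log2 signal relative to the array's 75th percentile), by line, with the mean and SD; n = 7 for low_RFI and 8 for high_RFI. Ribosomal proteins average 7.76 in low_RFI and 7.63 in high_RFI, fatty acid genes 2.36 and 2.51.

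In all, 6 of 30 lists were called by camera, 3 in each direction. Camera with an estimated correlation, fry and the exact permutation test each called 0, and the smallest exact adjusted p was 0.19. Random splits of the same pigs into groups of these sizes called a median of 6 lists by camera, and only 2 of them called none. The number of camera calls is thus no more than such splits gave.

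Of the other metabolic lists, none was called by camera, and no member passed limma over all genes. Glycolysis genes had a mean of 0.00061 (camera adjusted p = 0.996): LDHA gave 0.12, GPI 0.096, the lactate transporter SLC16A3 -0.20, well above background on 7 of 15 arrays and -0.043 without low_RFI replicate 2, and the glucose transporter SLC2A1 0.15 but -0.040 with normexp. Glycogen metabolism gave -0.044 (0.581), with the kinase subunits PRKAG1 at -0.26, PRKAA2 at 0.19 and PRKAG3 at 0.72 (0.43 without low_RFI replicate 3) and the enzyme PGM1 at -0.50 (-0.29 without low_RFI replicate 7). Citric acid cycle genes gave -0.095, with 12 of 15 higher in high_RFI (camera adjusted p = 0.0891, and adjusted p = 0.975 with an estimated correlation). Camera called them in 10 alternatives, such as slide as a block (-0.10, adjusted p = 0.0152) and quantile normalization (-0.11, 0.0121). Without the lowest low_RFI pig, replicate 3 (level 3.96), or the highest high_RFI pig, replicate 7 (4.59), the difference shrinks and was not called. Mitochondrially encoded transcripts gave -0.013 (0.723; median 0.0046), calcium handling -0.060 (0.38) and amino acid catabolism 0.0052, where the median of -0.0058 and the test pointed to high_RFI (0.782).

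Of the lists on protein turnover and growth, none was called either. Insulin, IGF and mTOR signalling gave 0.0085 (camera adjusted p = 0.945), with the mTOR inhibitors DEPTOR at 0.33 and DDIT4 at -0.30, the growth factor IGF1 at 0.22 and the adaptor GRB10 at -0.23, or -0.12 without low_RFI replicate 7. Proteasome subunits gave 0.040 (0.861), with PSMA5 at 0.16, PSMD3 at -0.12, PSMD10 at 0.18 and PSMB6 at 0.12. Proteolysis and autophagy gave -0.0012 (0.817), with BECN1 at -0.27, the cathepsins CTSZ and CTSV at -0.34 and 0.22 and the ubiquitin ligase NEDD4 at 0.39, or 0.11 with normexp. Antioxidant genes gave -0.042 (0.817; median 0.011), with the peroxiredoxins PRDX4 at 0.33 and PRDX3 at -0.25, SOD2 at -0.29 and SELENOP at 0.12, and 1 of 15 PRDX3 probes and 2 of 10 SELENOP probes pointed the other way. Translation factors gave 0.070 (0.38), though camera called them with normexp (0.099, adjusted p = 0.0324). Myogenesis genes gave -0.015 (0.945, median 0.018).

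Markers of other cell types in the muscle did not pass with all pigs. Adipocyte genes gave -0.092 (camera adjusted p = 0.0917), but passed without low_RFI replicate 7 (-0.19, adjusted p = 0.0016) or high_RFI replicate 3 (-0.16, 0.0155). Those pigs were the highest of low_RFI (0.98) and the lowest of high_RFI (0.042). Without the lowest of low_RFI, replicate 2 (0.023), or the highest of high_RFI, replicate 5 (0.85), the difference shrinks and was not called. With all pigs the adipocyte genes had adjusted p = 0.975 with an estimated correlation and 0.996 in the exact permutation test. Among them the glycerol channel AQP7, chosen after its value was seen, gave -1.14 ± 0.31 SE (2.21-fold higher in high_RFI) and passed limma adjusted over the list alone (adjusted p = 0.0478). Extracellular matrix gave 0.012 with a median of -0.046 (0.817), leukocytes 0.11 with a median of -0.10 (0.817), endothelium -0.020 (0.817), erythrocytes 0.00067 with the test toward high_RFI (0.861) and nerve -0.017 with a median of 0.026 (0.996). Complement and acute phase genes gave -0.29 (0.112), antigen presentation -0.11 (0.266) and interferon response -0.030 (0.723). Without low_RFI replicate 6 camera called all 3, at -0.34 (adjusted p = 0.0387), -0.30 (0.000172) and -0.24 (0.00735). High_RFI replicate 5 stood out as much, at 3.29 against 3.11 for antigen presentation and 1.97 against 1.63 for interferon response. Leaving it out moves those differences toward low_RFI instead, and camera then called none of the 3. With all pigs each of the 3 lists had adjusted p = 0.975 with an estimated correlation. Of the signs of handling and time of day, immediate-early genes gave 0.13 (0.861) and circadian clock genes -0.11 (0.777).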

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

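All tests of this part were chosen before the data were examined. In 204 groups of 7 or 8 pigs, over named genes and lists, a pig was looked for whose gap to its nearest neighbour took up an unusual share of the line's range; 12 groups had one, and chance gives about 10. High_RFI replicate 5 accounts for 4 of the 12, and these are given as values with no explanation tested.

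Among genes, SLC7A11 was low in high_RFI replicate 6, at a level of -7.03 against a mean of -5.49 in the others (share 0.571). PRIM2 was low in low_RFI replicate 1, at -2.71 against -2.46 (0.572). NDUFB9 was low in high_RFI replicate 5, at 6.29 against 7.12 (0.589). MYOZ2 was low in high_RFI replicate 3, at 3.30 against 5.37 (0.537). SLC2A1 was high in high_RFI replicate 5, at -2.22 against -2.87 (0.554). SLC16A3 was low in low_RFI replicate 2, at -6.11 against -4.99 (0.573).

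Among lists, glycolysis was low in high_RFI replicate 5, at 4.65 against 5.05 (0.662). Antigen presentation was high in high_RFI replicate 5, at 3.29 against 1.93 (0.578), and in low_RFI replicate 6, at 3.11 against 1.81 (0.578). Endothelium and pericyte markers were high in high_RFI replicate 4, at 1.65 against 1.32 (0.632), as were cell cycle genes, at -0.30 against -0.73 (0.699). Erythrocyte genes were low in high_RFI replicate 6, at -3.40 against -2.59 (0.57).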

How the results depend on the processing

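The blocks for runs of pig numbers and the list without NIFK were chosen only after the results were seen. MTERF3, the gene that passed, kept its direction in all 30 alternatives. The count of genes was 0 with normexp, median centring, deposited values, no filter on dim probes, slide as a fixed block, the replicate block, and either block for runs of pig numbers. It was 2, both symbols of the 1 gene MTERF3, with quantile normalization, array weights, the mean of a gene's probes or an adjusted p under 0.10, 82 at an unadjusted p under 0.01, and 0 to 3 leaving out each pig (3 without low_RFI replicate 2, MTERF3 under both symbols and NUDT2; 2 without high_RFI replicate 5, MTERF3 and HSDL2). MTERF3 was lost without low_RFI replicate 1, 3, 4 or 7, or high_RFI replicate 1, 2, 3, 4, 7 or 8 (adjusted p 0.0661 to 0.13). The count of probes was 1 with no filter, 548 at an unadjusted p under 0.01, and 0 to 2 leaving out each pig (2 without low_RFI replicate 7). Lists called by camera were 0 with an estimated correlation, 0 by fry, and 4 to 10 leaving out each pig (10 without low_RFI replicate 6, adding antigen presentation, interferon, complement and citric acid cycle genes). Normexp gave 4 lists, all higher in low_RFI, 3 of them shared with the 6 and the other translation factors. With normexp oxidative phosphorylation reversed in the test at a mean of -0.0071. Other fits of all 15 pigs by camera kept the 6. The replicate block gave 5 lists, but replicate numbers do not pair the pigs: same-number correlations ran from -0.012 to 0.271. That fit also left out high_RFI replicate 8, which has no low_RFI pig of its number. Leaving out that pig alone also ended the calls of oxidative phosphorylation (camera adjusted p = 0.11) and MTERF3 (limma adjusted p = 0.115). Of 187 comparisons for called lists 163 kept direction and call, and of 2095 for named genes 2069 kept direction and side of the threshold. Among named genes only MTERF3 was called with all pigs, so for the others staying uncalled counted as kept. MTERF3 itself lost its call in 18 of 30 alternatives. Per-pig list levels gave 0 throughout. No scaling moved the median gene by over 0.1, from 0.016 to between -0.021 and 0.020. The cause of these changes was not tested. All arrays had 1 scan date, so that block was not run. Signal over background limits dim genes: SLC16A3 and SLC7A11 were well above it on 7 and 8 arrays.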

Other observations

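The comparisons between runs of pig numbers, and the tests of leukocyte content, of neighbouring genes, of the counts of probes and genes over other splits and of splits balanced by run, were chosen only after the results were seen. Antiviral and immune genes were on average higher in pigs numbered 55 to 62 (n = 7, both lines) than in pigs numbered 1 to 8 (n = 8, both lines), with some overlap between pigs. What the numbers stand for is not in the labels. All 25 interferon response genes were higher in 55 to 62, by a mean of 1.15, with a level of 0.97 ± 0.62 (SD, n = 7) against -0.18 ± 0.35 (SD, n = 8), and 12 passed limma. RSAD2, an antiviral enzyme, was 3.56-fold higher, the ubiquitin-like modifier ISG15 2.88-fold, MX2 2.60-fold, USP18, which removes ISG15, 2.42-fold, and the RNA sensors IFIH1 and DDX58 2.23-fold and 2.20-fold (adjusted p from 0.00783 to 0.0194). Camera called the list (adjusted p = 2.6e-21), with adjusted p = 0.278 with an estimated correlation and 0.0122 in an exact permutation test over pigs within lines.

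Antigen presentation genes were higher in 55 to 62 in 21 of 23 members, by 0.79 (exact permutation adjusted p = 0.0122), among them the class II genes SLA-DRA and SLA-DQB1, 2.13-fold and 2.16-fold, and CD74, 1.98-fold. Leukocyte markers gave 0.91 in 18 of 20 members (exact adjusted p = 0.0122), with the T cell receptor subunit gene CD3D at 1.27, which did not pass limma (adjusted p = 0.0686), and FCGR1A, an interferon-induced Fc receptor, at 2.77 (0.0117). Within 55 to 62, high_RFI replicate 5 and low_RFI replicate 6 stood highest in both lists. Their leukocyte levels were -0.46 and -0.52, against -2.06 to -1.37 in the others. For antigen presentation they were 3.29 and 3.11, against 2.07 to 2.35. The comparison between runs was not repeated without these pigs. Of 11 T cell and myeloid markers, none of them in another list, CD2 of T cells passed limma (2.05, adjusted p = 0.033). Those of highest probe signal, which does not rank abundance across genes, were AIF1 (level 0.92 in 1 to 8 and 1.99 in 55 to 62), C1QA (0.48 and 1.46) and CD163 (0.87 and 1.32). Nerve markers gave 0.32 (exact adjusted p = 0.0122) and circadian clock genes 0.25 (0.0196), but camera called neither (adjusted p = 0.0759 and 0.501). Ribosomal proteins gave -0.086, higher in 3 of 39 members (camera 0.0281, exact 0.121), and complement genes 0.41 (camera 0.0281, exact 0.0735). Fast fibre proteins gave -0.24, lower in all 13 members (exact adjusted p = 0.0429, camera 0.0151), with the calcium buffer PVALB 1.74-fold higher in 1 to 8, and slow fibre proteins 0.40, higher in 11 of 14 (exact 0.309, camera 0.00542). With an estimated correlation the smallest adjusted p of these lists was 0.278. In all 173 genes passed limma between the runs, against 1 between the lines: 103 higher in 55 to 62 and 70 higher in 1 to 8, and 717 probes did. They were not all immune genes. The homeobox gene HOXA11 gave 4.27 (19.3-fold higher in 55 to 62, limma adjusted p = 0.0383). LDHC was 3.30-fold higher in 1 to 8 (0.0403). The genes named here were chosen after their values were seen. Some were dim in 1 run: FCGR1A and CD2 had levels of -6.36 and -5.39 in 1 to 8, and LDHC -5.49 in 55 to 62. Between the lines, the dim gene SLC7A11 fell from 1.18 to 0.028 with normexp. The comparison between runs was not repeated with normexp, so the size of such differences is uncertain.

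The interferon difference between runs was set against slide, line and leukocyte content as possible sources. Within slides it was at least 0.734 (1.09, 2.33, 0.734 and 0.953), which argues against slide as its cause. It was 1.23 within high_RFI (4 pigs of each run) and 1.07 within low_RFI (3 pigs of 55 to 62 and 4 of 1 to 8). The lines were spread so evenly over the runs that line could hardly have made it. Leukocyte content stays open: the interferon genes' median of 1.14 exceeded that of 11 T cell and myeloid markers by 0.0734. The 95% interval of this gap was -0.576 to 0.419 from resampling genes. Those markers ranged from 0.065 for CD14 to 2.05 for CD2, so their median mixes cell types and unlike differences. Health status, age, litter and day of slaughter are not in the labels and were not tested.

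The gene lists called between the lines could reflect chance or the structure of the samples. Among 100 splits of the 15 pigs, the real one included, 60 called as many lists as the 6 of the lines, and the highest other split called 14, so chance is not excluded for their number; over 100 splits that take as many pigs from each run as the lines do, 49 did (highest other 16). The ribosomal protein list gave 0.123, and 0.119 ± 0.0134 (SE over genes) after subtracting the median of 200 genes of like brightness. That argues against brightness as its source. The SE takes genes as independent, though their estimated correlation was 0.474, so it is too small. The size of the difference did depend on the processing, at 0.076 with quantile normalization and 0.18 with normexp. Line as a biological cause stays open.

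For single genes, 5 of 100 splits gave as many as the 1 gene that passed, and the highest other gave 13. These splits took no account of the runs. The other splits that called a gene were uneven by run, with 5 and 3, 2 and 6, 5 and 3, and 1 and 7 pigs from 1 to 8. Most of the splits that called none were uneven too, and 2 other splits balanced by run called a gene. Unevenness alone therefore does not account for such calls. For probes at an unadjusted p under 0.01, 10 gave as many as the 548 of the lines (highest other 1189), so chance is not excluded for either count. Since 0 probes were called, all 100 splits necessarily gave as many, with 41 in the highest other, and that count tests nothing. Over the 100 splits balanced by run, the real one included, 3 gave as many genes (highest other 1). As many probes at an unadjusted p under 0.01 came from 5 (highest other 650). The rule, set after the results were seen, counts fewer than 5 in 100 against chance. By it 3 counts against chance for genes, and 5 does not for probes. Both lie near that limit, so chance stays open. The split with 41 probes and 13 genes nearly followed the runs of pig numbers, with 1 of its 7 and 7 of its 8 pigs from 1 to 8. Another split of that make-up called 0 probes and 0 genes, though it gave the highest count at an unadjusted p under 0.01 (1189). So few splits of that make-up cannot tell whether the runs explain the 13 genes. With run as a block, limma gave 0 genes between the lines, MTERF3 at -0.57 (adjusted p = 0.0525).

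A hypothesis that genes of small p cluster in linked regions, as selection on a line could produce, was tested on 79 placed genes at an unadjusted p under 0.01. They formed 14 pairs within 10 positions of each other among the tested genes, against a mean of 13.3 in random draws, and 45.4% of 10000 draws gave as many. Of 100 splits 40 gave a share as small (highest other 103 pairs). The excess that the hypothesis predicts was not seen. How to read such a value was decided after it was seen, and a lack of excess does not exclude the hypothesis, so the question stays open.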
